A study of Rattus norvegicus with 12 samples.

How the data were processed

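Gene expression was measured with Affymetrix arrays in cultures of neonatal rat heart muscle cells exposed to di(2-ethylhexyl) phthalate (DEHP), a plasticiser of polyvinyl chloride. Per the labels' protocols, cells came from Sprague-Dawley pups 2 days old, grew for 3 days after enzymatic isolation, and were then treated for 3 days with DEHP at 1, 10 or 50 µg/ml in 0.1% dimethyl sulphoxide, or with 0.1% dimethyl sulphoxide alone. Each of the 4 groups had 3 arrays, 12 in all, with 1 array per sample and cRNA made from 5 µg of total RNA. The series description calls the arrays of a group biological replicates and says that all cells came from the same litter, so the p-values measure the spread between cultures of 1 litter.

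Per the submitters' processing notes, the arrays were processed with RMA (robust multi-array average), which corrects background, applies quantile normalization and summarises the probes of a probe set. Its version is not given in the sources used here. The deposited values are linear ratios: each array's value was divided by the median of the same probe set over the 12 arrays. This was found from the values, since the log midpoint of the 6th and 7th of the 12 values of every probe set was 0 to within 1e-06. The values ran from 0.165 to 12.2. The median of each array's values lay between 0.994 (1 µg/ml, replicate 3) and 1.01 (10 µg/ml, replicate 2). The scale and the centring were therefore settled from the values, whereas the direction (array over median, so that a larger value means more RNA) was taken as read and no source used here records it.

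The ratios were converted to log2. Differences between arrays for a probe set survive this centring, but the level of each probe set is lost. The design fixed beforehand had assumed log2 levels, and several of its steps changed for that reason. A filter on dim probe sets was not run, because no mean intensity remained to rank them by. A gene with several probe sets was represented by the mean of its probe sets in place of the brightest of them, which applied to 499 of 14324 genes. No detection call, background correction, scan date or slide was analysed here, so nothing is known about how far a probe set lay above background. Control probe sets were not told apart from others, and all 27342 probe sets were tested.

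Probe sets were named from the platform annotation: 15097 had 1 gene symbol, 323 had several and 11922 had none, and no gene was named from a probe set with several. Symbols were looked up by Entrez identifier in the GRCr8 gene table, which held 15067 of the probe sets, and the lookup changed 0 symbols. Precision is limited by the number of arrays. The median residual SD of a probe set was 0.08 on the log2 scale.

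Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, followed by empirical Bayes moderation with a constant prior variance. The fit had 8 residual degrees of freedom. Each dose was compared with the vehicle and with each other dose. A linear trend over the dose order and a moderated F statistic over the 4 groups were also tested. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets, or over all 14324 genes for gene results, with a threshold of 0.05. All adjusted p-values of single genes come from limma. An exact permutation of 3 arrays against 3 cannot give a p under 0.1, so the comparisons rest on the moderated model.

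Of the 30 gene lists fixed before the data were examined, covering metabolism, contraction, matrix, stress and markers of other cell types that a heart culture can hold, 924 of 1073 entries (86.1%) were measured. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 30 lists within each comparison, and again with the correlation estimated for each list. No list passed at any dose with the estimated correlation. The estimates ran from 0.004 to 0.466 over the lists, so p-values at the preset correlation can be far too small. The number of list members past the threshold is given over all genes and adjusted over the list alone.

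Genes to be named were also set beforehand. From genes past the threshold whose 3 arrays in one group all lay on one side of the 3 in the other, the rule took the 8 largest rises and 8 largest falls at 50 µg/ml, 4 and 4 at each lower dose, and 2 and 2 between doses. Where none passed, it took the 4 with the smallest unadjusted p. It added the 3 members with the smallest p from each list that passed camera, and a panel of 22 genes of fatty acid metabolism, contraction, coupling and matrix, of which 19 were measured and the others are not reported here. A few other list members are given as examples and were chosen after their values were seen.

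Alternatives planned beforehand were quantile normalization applied again, centring of each array on its median, 2 other forms of empirical Bayes moderation, array weights, fits with the compared groups alone, the replicate number as a block, 1 value per gene, omission of each array in turn, dose itself as trend score, the estimated correlation, and a minimum change of 1.5-fold. Restriction to genes with 1 probe set was added after seeing the data. For probe sets called at 50 µg/ml, the values at the lower doses were set against 50 simulated sets of 4 groups with the measured residual SDs, no change at 1 and 10 µg/ml and the measured changes at 50 µg/ml. Other splits of the arrays were counted, all 10 for 3 against 3 and 100 random assignments for the tests over 4 groups.

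The fit was tested on simulated data before use, with 50 of the 27342 probe sets changed at each of several fold sizes. For 50 µg/ml against control it called 52% of changes of 1.25-fold, 96% of 1.5-fold, 98% of 2-fold and 100% of 3-fold, with 11 false calls. For 10 µg/ml the shares were 52%, 92%, 100% and 100%, with 15 false calls, and for 1 µg/ml 58%, 98%, 98% and 100%, with 14. The simulated probe sets were independent and had the same spread in every group. The measured arrays had unequal spreads, so these shares need not hold for them, nor explain the count at 10 µg/ml. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.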

Results

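The arrays followed the response of neonatal rat heart muscle cell cultures to 3 days of the plasticiser DEHP at 1, 10 or 50 µg/ml, set against the vehicle, with 3 arrays in each of the 4 groups. The series title asks for dose dependence, so each dose was compared with the vehicle and with each other dose. Values below are differences of log2 ratios with their standard errors, n = 3 arrays per group throughout, and the number of arrays limits their precision. The deposited ratios were read as array over median, which no source used here records, and with the ratio turned each rise given here would be a fall of equal size. The deposited values carry no level, so whether a gene was near background was not analysed here. At 50 µg/ml 3336 probe sets changed, at 1 µg/ml 893 and at 10 µg/ml 0.

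**Figure D1:**
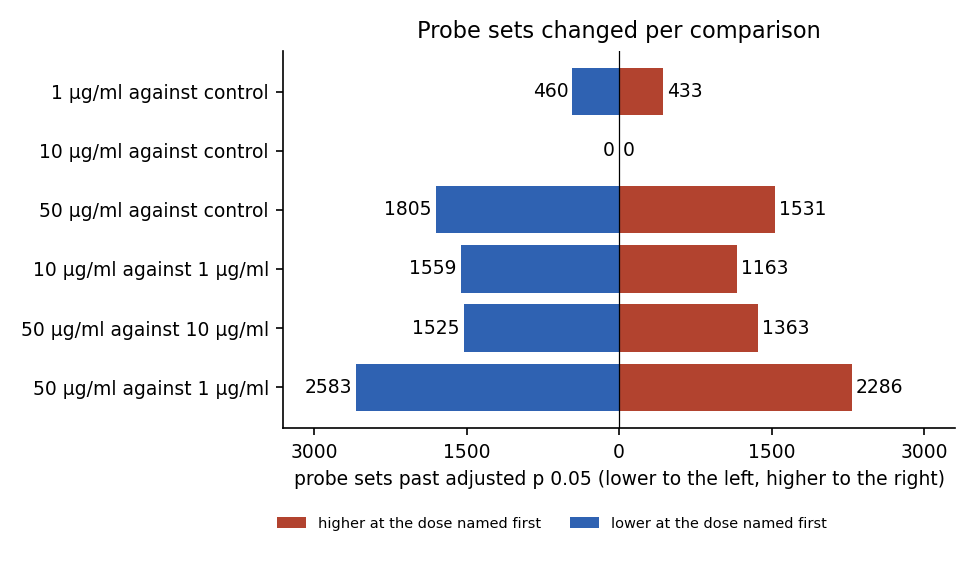
Bars give the number of probe sets past an adjusted p of 0.05 in each of 6 comparisons, lower to the left and higher to the right on the horizontal axis. The comparison of 50 µg/ml with control has 1531 higher and 1805 lower probe sets, that of 1 µg/ml 433 and 460, and that of 10 µg/ml 0 and 0.

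The comparison of 50 µg/ml with the vehicle asked what differed at the highest dose. The macrophage list (21 of 27 members lower) and the cell cycle list (32 of 52 lower) shifted down. The inflammatory (18 of 42 higher), oxidative stress (13 of 40), sarcomere (15 of 34) and mitochondrial fatty acid oxidation lists (13 of 26) shifted up. Each passed camera at the preset correlation and none did with an estimated one. Another split of the same 6 arrays gave 13 lists at the preset correlation, as many as the real split. The largest rise was that of Pla2g2a, a secreted phospholipase A2, by 2.88 ± 0.24 (adjusted p = 4.56e-06). Npy, which encodes neuropeptide Y, rose by 2.46 ± 0.12, the complement component C6 by 2.08 ± 0.11, the nuclear receptor Nr4a1 by 1.83 ± 0.11, the atypical chemokine receptor Ackr3 by 1.63 ± 0.08 and the surface glycoprotein Cd24 by 1.49 ± 0.07. The metallothioneins Mt1 and Mt2A, small proteins that bind metal ions, rose by 1.82 ± 0.09 and 1.58 ± 0.10. Of 21 immediate early genes, a set that holds Nr4a1 and was chosen after results were seen, 16 were higher (median 0.39). Handling of the cultures cannot be told apart from dose at 50 µg/ml.

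Among falls at 50 µg/ml, the protease inhibitor A2m fell by 2.51 ± 0.24 (adjusted p = 1.68e-05) and the macrophage lysozyme Lyz2 fell by 2.32 ± 0.13 (adjusted p = 1.67e-07). The granin Scg2 fell by 1.91 ± 0.10, Vof16 fell by 1.85 ± 0.13, the G protein regulator Rgs18 fell by 1.81 ± 0.13 and Csf1r, the receptor of colony stimulating factor 1, fell by 1.78 ± 0.09. Ch25h, a hydroxylase of cholesterol, fell by 1.70 ± 0.10 and Prss3bl1 fell by 1.69 ± 0.12. The naming rule required the 3 treated arrays of each of these 16 genes to lie on one side of the 3 controls, so this separation is no added support. Under limma, 1531 probe sets were higher and 1805 lower, and of 14324 genes 1254 were higher and 1266 lower. The groups did not overlap in 36.0% of genes, against 10% by chance. The probe set count was 2199 without control replicate 1. A repeated quantile normalization, which forces arrays to 1 spread, reduced the largest changes by more than 1.5 times, to 1.51 for Pla2g2a, 1.52 for Npy, 1.37 for C6, 1.18 for Mt1, -1.49 for A2m, -1.43 for Lyz2, -1.13 for Rgs18, -0.955 for Aldh1a1 and -0.786 for Ltbp2. Pla2g2a lost its call when the prior variance followed the mean (adjusted p = 0.256, with 1.22e-06 to 0.256 over its alternatives).

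**Figure D2:**
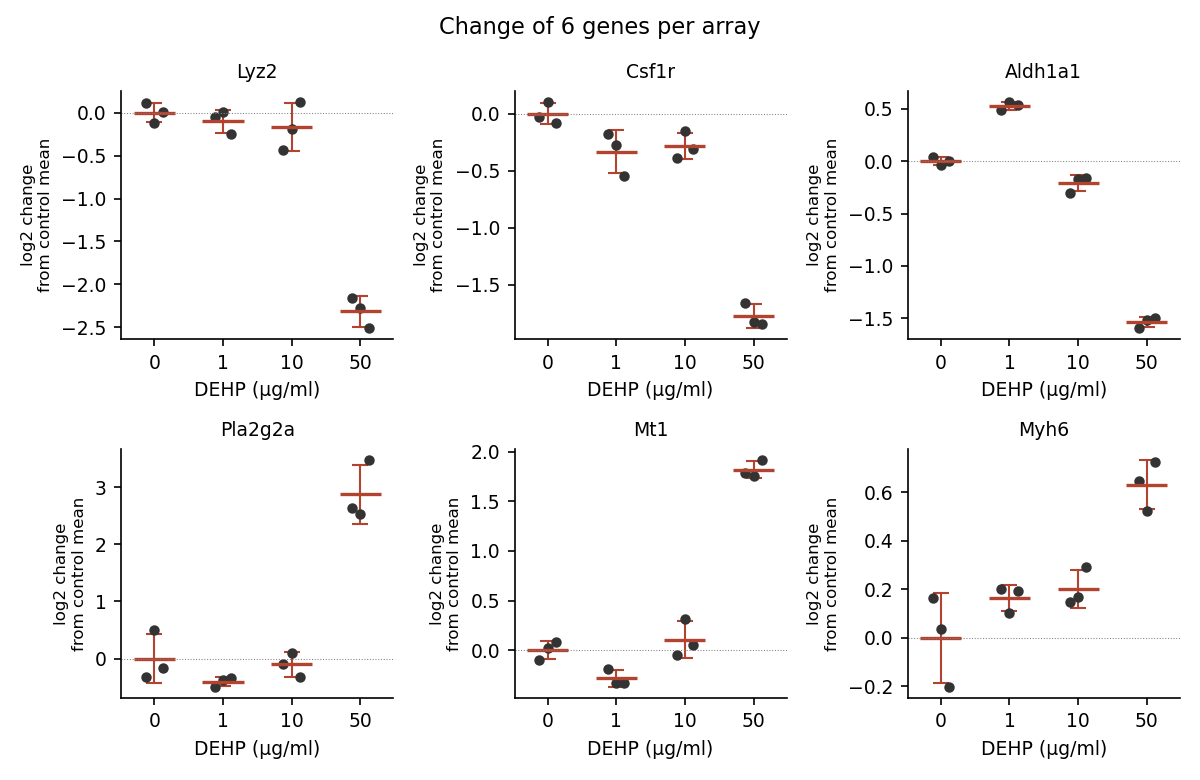
Each point is 1 array's log2 change from the control mean (vertical axis) by DEHP dose in µg/ml (horizontal axis) for 6 genes, with the group mean as a bar and 1 SD as error bar. All 3 arrays at 50 µg/ml lie below the other 9 for Lyz2, Csf1r and Aldh1a1 and above them for Pla2g2a, Mt1 and Myh6.

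Markers of macrophages and other leukocytes had a median change of -1.02 at 50 µg/ml, with 21 of 27 lower, 0 higher and 6 not past the threshold, and 21 lower adjusted over the list alone (camera adjusted p = 4.77e-22). With an estimated correlation the adjusted p was 0.0846. Besides Lyz2 and Csf1r, the actin-bundling protein Lcp1 fell by 1.41 ± 0.07, the leukocyte phosphatase Ptprc fell by 1.53 ± 0.10 and the complement subunit C1qa fell by 1.62 ± 0.15. Cd3e of T cells and Cd79b of B cells had values of 0.02 and 0.03, and neither passed the threshold. Other cell types moved apart from the macrophage list. Of 14 endothelial markers 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.019; adjusted p = 0.455 with an estimated correlation). The cadherin Cdh5 rose by 0.57 ± 0.12 and the transcription factor Sox17 by 0.25 ± 0.07, while the growth factor receptor Flt1 fell by 0.29 ± 0.07. Of 12 epicardial and mesothelial markers 4 were higher and 0 lower, 4 adjusted over the list alone (median 0.18, camera adjusted p = 0.0131; adjusted p = 0.33 with an estimated correlation). Upk1b rose by 0.80 ± 0.12, Gpm6a by 0.75 ± 0.13 and Aldh1a2 by 0.39 ± 0.09. The endothelial list missed the threshold after a repeated quantile normalization (adjusted p = 0.0655, with 0.00484 to 0.0655 over its alternatives). Fibroblast markers (3 higher and 4 lower of 23; 3 and 5 adjusted over the list alone), smooth muscle and pericyte markers (5 and 5 of 16; 5 and 5), erythroid markers (1 and 0 of 12; 0 and 0) and neuronal markers (3 and 0 of 19; 3 and 0) did not pass as lists, with camera adjusted p of 0.301, 0.82, 0.112 and 0.105.

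**Figure D3:**
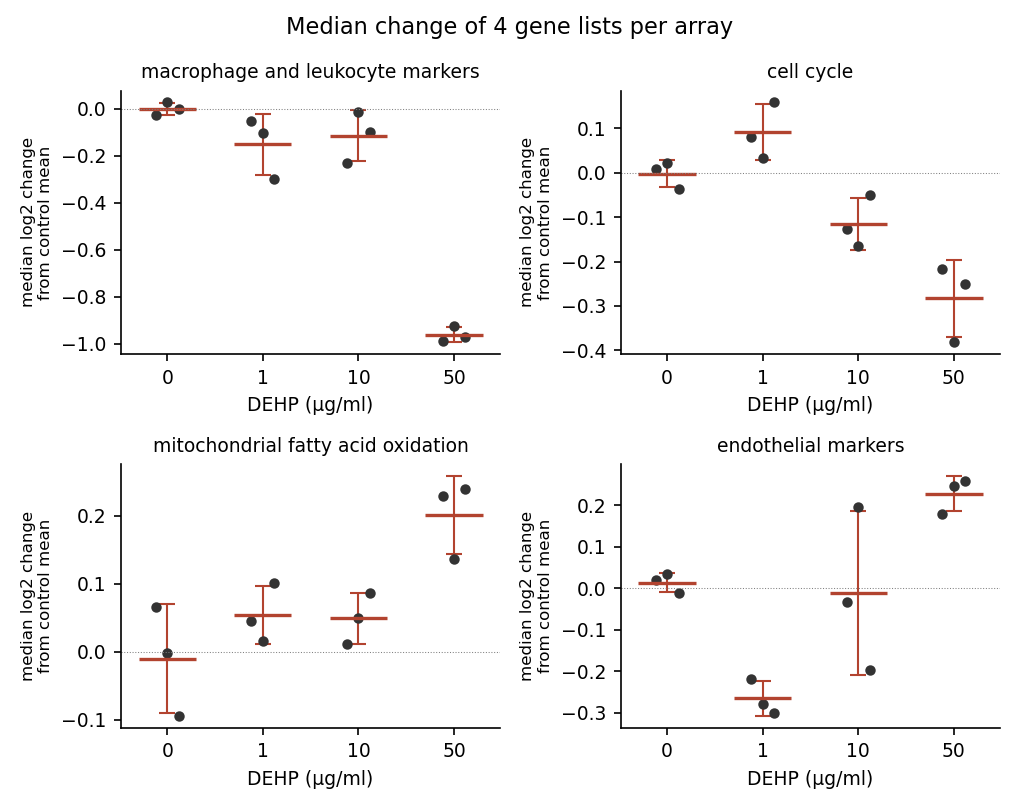
Each point is 1 array's median log2 change from the control mean over a gene list (vertical axis) by DEHP dose in µg/ml (horizontal axis), with the group mean as a bar and 1 SD as error bar. For macrophage and leukocyte markers the highest array at 50 µg/ml stands at -0.924 and the lowest other array at -0.3.

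Cell cycle genes had a median of -0.28 at 50 µg/ml, in cultures where macrophage markers were also lower at -1.02. Of 52 measured, 32 were lower, 1 was higher and 19 were not past the threshold, and adjusted over the list alone 39 were lower and 1 higher (camera adjusted p = 6.69e-16; adjusted p = 0.198 with an estimated correlation). The mitotic kinase Plk1 fell by 0.48 ± 0.05, the kinase Aurka fell by 0.54 ± 0.06 and the cyclin Ccnf fell by 0.61 ± 0.07, whereas the G1 kinase Cdk4 rose by 0.24 ± 0.06.

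The sarcomere, mitochondrial fatty acid oxidation, oxidative phosphorylation and cholesterol synthesis lists were higher at 50 µg/ml, in cultures where macrophage markers stood at -1.02, whereas glycolysis, the tricarboxylic acid cycle, fatty acid synthesis, fatty acid uptake and peroxisomal fatty acid oxidation did not pass (camera adjusted p of 0.112 to 0.442). Of 34 sarcomere genes 15 were higher, 1 was lower and 18 were not past the threshold, with 16 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.000136; adjusted p = 0.455 with an estimated correlation). The atrial light chain Myl7 rose by 1.45 ± 0.10, the ventricular light chain Myl2 by 0.56 ± 0.06 and the alpha myosin heavy chain Myh6 by 0.63 ± 0.08. Mitochondrial fatty acid oxidation had 13 higher, 0 lower and 13 not past the threshold of 26, and 15 higher adjusted over the list alone (median 0.19, camera adjusted p = 1.07e-05; adjusted p = 0.33 with an estimated correlation). The acyl-CoA synthetase Acsl1 rose by 0.62 ± 0.09, the isomerase Eci2 by 0.37 ± 0.06 and the dehydrogenase Acadl by 0.34 ± 0.08. Oxidative phosphorylation had 10 higher and 0 lower of 65, and 2 higher adjusted over the list alone (median 0.11, camera adjusted p = 5.14e-05; adjusted p = 0.455 with an estimated correlation). The complex I subunits Ndufb8, Ndufb10 and Ndufa11 rose by 0.24 ± 0.05, 0.26 ± 0.06 and 0.26 ± 0.07. Cholesterol synthesis had 7 higher and 0 lower of 19, and 9 higher adjusted over the list alone (median 0.20, camera adjusted p = 0.0021; adjusted p = 0.455 with an estimated correlation). Tm7sf2 rose by 0.58 ± 0.08, Insig1 by 0.73 ± 0.11 and the epoxidase Sqle by 0.38 ± 0.07.

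The inflammatory, oxidative stress and xenobiotic metabolism lists were also higher at 50 µg/ml, where macrophage markers stood at -1.02, whereas the unfolded protein response list did not pass (camera adjusted p = 0.359). Of 42 inflammatory and interferon response genes 18 were higher, 3 lower and 21 not past the threshold, with 23 and 5 adjusted over the list alone (median 0.18, camera adjusted p = 5.14e-05; adjusted p = 0.33 with an estimated correlation). Besides Pla2g2a, the NF-kappaB inhibitor Nfkbia rose by 0.79 ± 0.05, the adhesion molecule Vcam1 by 1.18 ± 0.14 and the chemokine Cxcl1 by 1.32 ± 0.15, while Socs3, an inhibitor of cytokine signalling, fell by 0.67 ± 0.05. Oxidative stress genes had 13 higher, 3 lower and 24 not past the threshold of 40, with 14 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.000289; adjusted p = 0.198 with an estimated correlation). Besides Mt1 and Mt2A, the haem oxygenase Hmox1 rose by 0.65 ± 0.06. Xenobiotic metabolism had 12 higher and 3 lower of 36, and 12 and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.0167; adjusted p = 0.198 with an estimated correlation). The hydroxylases Cyp27a1 and Cyp7b1 rose by 0.44 ± 0.05 and 0.81 ± 0.10, and the retinal dehydrogenase Aldh1a1 fell by 1.54 ± 0.05.

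At 50 µg/ml, where the macrophage, endothelial and epicardial lists stood at -1.02, 0.21 and 0.18, genes of fetal heart and hypertrophy had 15 higher and 5 lower of 33, with 16 and 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.0065; adjusted p = 0.33 with an estimated correlation). Besides Myl7, which is also on the sarcomere list, the transcription factors Egr1 and Myc rose by 1.44 ± 0.13 and 0.47 ± 0.05. Both are also in the immediate early set. The natriuretic peptide Nppa fell by 0.17 ± 0.05 and the embryonic myosin Myh3 fell by 1.39, while Nppb (0.06) and Myh7 (0.19) did not pass. The list shift therefore does not stand for these genes. The extracellular matrix list moved down, with 12 lower, 4 higher and 26 not past the threshold of 42, and 13 and 6 adjusted over the list alone (median -0.09, camera adjusted p = 0.0187; adjusted p = 0.455 with an estimated correlation). The latent TGF-beta binding protein Ltbp2 fell by 1.22 ± 0.08 and the proteoglycan Vcan fell by 0.73 ± 0.08, while fibulin Fbln1 rose by 1.00 ± 0.07. This list missed the threshold without 50 µg/ml replicate 3 (adjusted p = 0.0758, with 0.0104 to 0.0758 over its alternatives), where its median was -0.043.

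The genes of the fixed panel were read at 50 µg/ml whether or not they passed. Besides Myh6, the carnitine transferases Cpt1a and Cpt1b rose by 0.24 ± 0.06 and 0.38 ± 0.11, the adhesion protein Cdh2 by 0.21 ± 0.06, the calcium release channel Ryr2 by 0.32 ± 0.08, the calcium pump Atp2a2 by 0.17 ± 0.05 and the protease Mmp2 by 0.27 ± 0.04. The natriuretic peptide Nppa fell by 0.17 ± 0.05. The receptors Ppara, Pparg and Ppard stood at 0.01, 0.03 and 0.10 and did not pass, nor did Pdk4 (-0.25), Angptl4 (0.16), Gja1 (0.13), Slc8a1 (0.13), Myh7 (0.19), Nppb (0.06), Col1a1 (0.01) and Timp1 (0.06). Of 56 named genes past the threshold at 50 µg/ml, 45 kept it in all 12 omissions of an array. Flt1, Sox17, Aldh1a2, Ndufb10, Ndufa11, Cpt1a, Cpt1b, Cdh2, Ryr2, Atp2a2 and Nppa lost it in at least 1. The losses numbered 3, 5 and 7 without control replicates 1, 2 and 3, and 4, 5 and 9 without 50 µg/ml replicates 1, 2 and 3. Without control replicate 3 Cpt1b stood at 0.251. A repeated quantile normalization ended the calls of Cdh5, Sox17, Cpt1b, Atp2a2 and Nppa.

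PPAR target genes did not pass as a list at 50 µg/ml (camera adjusted p = 0.3), with 10 of 35 higher and 4 lower, 10 and 4 adjusted over the list alone. Their members went both ways, the lipase Lpl rising by 0.56 ± 0.10 while Txnip fell by 1.20 ± 0.07. Calcium handling had 10 higher and 4 lower of 37 (10 and 5 adjusted over the list alone, camera adjusted p = 0.0677), cardiac ion channels 10 and 5 of 33 (10 and 5, 0.226), intercalated disc and gap junctions 9 and 2 of 28 (10 and 2, 0.081) and matrix proteases 10 and 5 of 32 (11 and 5, 0.284). Peroxisomal fatty acid oxidation had 3 and 0 of 29 (2 and 0, 0.335), fatty acid uptake 8 and 6 of 33 (10 and 8, 0.442), fatty acid synthesis 6 and 2 of 17 (6 and 2, 0.174), glycolysis 4 and 1 of 29 (4 and 1, 0.209) and the tricarboxylic acid cycle 4 and 0 of 27 (4 and 0, 0.112). Kinesins and tubulins had 7 and 2 of 42 (7 and 2, 0.27), the unfolded protein response 8 and 7 of 37 (12 and 8, 0.359) and p53 targets 6 and 4 of 31 (8 and 4, 0.576). None of these passed camera. For the smooth muscle and p53 lists the median, at -0.03 and -0.02, and the mean, at 0.04 and 0.06, differed in sign. So did median, mean or test for glycolysis and ion channels at 1 µg/ml and for kinesins, PPAR targets and the tricarboxylic acid cycle at 10 µg/ml.

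The comparison of 1 µg/ml with the vehicle asked what differed at the lowest dose, where handling of the cultures cannot be told apart from dose either. The transcription factors Fos, Egr1 and Egr2 rose by 1.56 ± 0.15 (adjusted p = 0.000277), 1.07 ± 0.13 and 0.78 ± 0.13, and the kinase Plk2 by 0.74 ± 0.09. Vof16 fell by 1.71 ± 0.13 (adjusted p = 3.92e-05), the stress-regulated Ddit4 fell by 1.17 ± 0.11, G0s2, an inhibitor of the triglyceride lipase Pnpla2, fell by 0.93 ± 0.09 and Clec2g fell by 0.92 ± 0.07. The naming rule required the 3 arrays of each group to be separate in each of these 8 genes. Of 893 probe sets, 433 were higher and 460 lower, and of 14324 genes 359 and 249. The groups did not overlap in 30.8% of genes, against 10% by chance. The probe set count was lower with any 1 array of the compared groups left out, where 2 arrays remain in a group, at 305, 330 and 283 without control replicates 1, 2 and 3 and 383, 522 and 342 without 1 µg/ml replicates 1, 2 and 3. It was 1906 without 10 µg/ml replicate 2, 1692 after a repeated quantile normalization, 2542 with array weights and 2178 with only the compared groups in the fit.

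Endothelial, macrophage and fibroblast lists were lower at 1 µg/ml under the preset correlation. With it 11 lists passed at this dose, and another split of the same 6 arrays gave 15. The lists are not independent, since the matrix and fibroblast lists share 8 genes and the fetal and sarcomere lists 7. Endothelial markers had a median of -0.25, with 4 of 14 lower and 0 higher, and 9 lower adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.387 with an estimated correlation). The cadherin Cdh5 fell by 0.66 ± 0.12, the receptor Tie1 fell by 0.59 ± 0.11 and Sox18 fell by 0.47 ± 0.09. Macrophage markers had a median of -0.19 (-0.129 without 1 µg/ml replicate 3), with per-array medians of -0.053, -0.102 and -0.3, and 3 of 27 were lower and 0 higher, and 4 adjusted over the list alone (camera adjusted p = 0.000146; adjusted p = 0.525 with an estimated correlation). The integrin Itgb2 fell by 0.37 ± 0.08, Laptm5 fell by 0.36 ± 0.09 and Itgam fell by 0.27 ± 0.07. Fibroblast markers had 3 of 23 lower and 0 higher, 4 lower and 1 higher adjusted over the list alone (median -0.05, camera adjusted p = 0.022; adjusted p = 0.54 with an estimated correlation). Mfap5 stood at -0.26 ± 0.06 and Pi16 at -0.35 ± 0.09. Extracellular matrix had 2 of 42 lower and 0 higher, 7 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.000841; adjusted p = 0.525 with an estimated correlation). These were Fbln1, which fell by 0.44 ± 0.07 and is also on the fibroblast list, and Ltbp2, which fell by 0.32 ± 0.08. Lama5 stood at -0.22 ± 0.06 and did not pass. Inflammatory genes had 6 of 42 lower and 2 higher, 9 and 3 adjusted over the list alone (median -0.06, camera adjusted p = 0.0093; adjusted p = 0.652 with an estimated correlation). Socs3 fell by 0.72 ± 0.05, and the chemokines Ccl2 and Ccl7 fell by 0.57 ± 0.07 and 0.80 ± 0.10.

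Higher at 1 µg/ml, where endothelial and macrophage markers stood at -0.25 and -0.19, was the sarcomere list, with 5 of 34 higher and 0 lower, 8 adjusted over the list alone (median 0.05, camera adjusted p = 0.00194; adjusted p = 0.7 with an estimated correlation). Lmod2 rose by 0.46 ± 0.07, Nexn by 0.41 ± 0.08 and Xirp2 by 0.49 ± 0.11. The per-array sarcomere medians overlapped, at 0.088, 0.027 and 0.093 for 1 µg/ml and 0.113, -0.017 and -0.074 for the controls. Cell cycle genes had 3 of 52 higher and 0 lower, 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.00241; adjusted p = 0.7 with an estimated correlation). Tpx2, Nuf2 and Ndc80 rose by 0.31 ± 0.06, 0.33 ± 0.08 and 0.44 ± 0.11. Fetal and hypertrophy genes had 5 of 33 higher and 1 lower, 7 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.012; adjusted p = 0.525 with an estimated correlation). Besides Fos and Egr1, Jun rose by 0.55 ± 0.08, and these genes are also in the immediate early set. Xenobiotic metabolism had 3 of 36 higher and 0 lower, 7 adjusted over the list alone (median 0.05, camera adjusted p = 0.0129; adjusted p = 0.387 with an estimated correlation). Aldh1a1 rose by 0.53 ± 0.05, Cyp2j4 by 0.40 ± 0.10 and the epoxide hydrolase Ephx1 by 0.37 ± 0.09. Oxidative stress genes had 3 of 40 higher and 1 lower, 9 and 4 adjusted over the list alone (median 0.07, camera adjusted p = 0.0212; adjusted p = 0.525 with an estimated correlation). The glutathione transferase Gstm2 rose by 0.41 ± 0.07, catalase (Cat) by 0.31 ± 0.06 and Srxn1 by 0.20 ± 0.04. Mitochondrial fatty acid oxidation had 1 of 26 higher and 0 lower, 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.0212; adjusted p = 0.712 with an estimated correlation). Acot2 rose by 0.46 ± 0.09, while Decr1 and Acot13 stood at 0.13 and 0.19 and did not pass. The per-array medians of the fatty acid oxidation list overlapped too, at 0.046, 0.016 and 0.101 against 0.066, -0.002 and -0.094 in the controls. Of the panel, Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 0.53 ± 0.12 at 1 µg/ml. The other 19 lists did not pass, with camera adjusted p of 0.0907 to 0.942.

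Many calls at 1 µg/ml were lost with 1 array fewer. Of 36 named genes past the threshold, 15 kept it in all 12 omissions of an array, and 21 lost it in at least 1. These were Tpx2, Nuf2, Ndc80, Cdh5, Tie1, Sox18, Ltbp2, Mfap5, Pi16, Itgb2, Laptm5, Itgam, Acot2, Gstm2, Cat, Srxn1, Nexn, Xirp2, Cyp2j4, Ephx1 and Pdk4. In these omissions the changes of the 36 genes were at least 0.721 times those with all arrays, and 0 genes moved by over 1.5 times either way. The losses numbered 16, 20 and 18 without control replicates 1, 2 and 3, 17, 9 and 17 without 1 µg/ml replicates 1, 2 and 3, 6 without 10 µg/ml replicate 1, and 6, 1 and 5 without 50 µg/ml replicates 1, 2 and 3. Median centring and robust moderation each ended the calls of Nuf2 and Ndc80, and a prior variance following the mean those of Ltbp2, Mfap5, Laptm5 and Itgam. Gstm2 stood at 0.627 after a repeated quantile normalization. Fibroblast markers and xenobiotic metabolism missed the threshold without 1 µg/ml replicate 1 (adjusted p = 0.107 and 0.0584), oxidative stress genes without 1 µg/ml replicate 2 (0.061) or 10 µg/ml replicate 2 (0.0542), cell cycle genes without 1 µg/ml replicate 3 (0.0974), and mitochondrial fatty acid oxidation without control replicate 3 (0.224) or 1 µg/ml replicate 3 (0.201). The cell cycle list also missed it after a repeated quantile normalization (0.0988). Oxidative stress (0.104) and mitochondrial fatty acid oxidation (0.055) missed it with only the compared groups in the fit. Over their alternatives with the preset correlation the adjusted p ran from 0.00965 to 0.107 for fibroblast markers, 0.00719 to 0.0584 for xenobiotic metabolism, 0.00275 to 0.104 for oxidative stress, 4.22e-05 to 0.0988 for the cell cycle and 0.00115 to 0.224 for mitochondrial fatty acid oxidation.

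Several list medians at 1 µg/ml moved by more than 1.5 times when an array was left out. Without control replicate 1 the median was 0.123 for the sarcomere, -0.093 for inflammatory genes, 0.099 for fetal and hypertrophy genes and 0.138 for mitochondrial fatty acid oxidation. Without control replicate 2 it was -0.03 for inflammatory and 0.024 for oxidative stress genes, and without control replicate 3 it was 0.028 for the sarcomere and 0.032 for mitochondrial fatty acid oxidation. Omission of 1 µg/ml replicate 1 gave 0.031 for xenobiotic metabolism and -0.035 for fibroblast markers. Omission of 1 µg/ml replicate 2 gave 0.08 for the sarcomere, 0.079 for xenobiotic metabolism, 0.042 for oxidative stress genes and 0.115 for mitochondrial fatty acid oxidation, which stood at 0.046 without 1 µg/ml replicate 3.

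At 10 µg/ml no probe set and no gene passed under limma. The counts at an unadjusted p under 0.05 were 1505 probe sets and 899 genes, and array weights gave 3 probe sets and a repeated quantile normalization 1. The genes with the smallest p were the embryonic myosin Myh3 at -0.89 ± 0.13 (adjusted p = 0.201), the calcium channel subunit Cacna2d2 at 0.41 ± 0.07, Sla at -0.35 ± 0.06 and Cpm at -0.29 ± 0.05 (adjusted p = 0.213 each). The groups did not overlap in 11.2% of genes, against 10% by chance. The count was 0 in all 12 omissions of an array.

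Lists nonetheless moved at 10 µg/ml under the preset correlation, 15 of 30, with no member past the threshold over all genes. The sarcomere list had a median of 0.15 (14 higher adjusted over the list alone, camera adjusted p = 4.95e-19; adjusted p = 0.207 with an estimated correlation). Oxidative phosphorylation had a median of 0.11 (2 higher adjusted over the list alone, camera adjusted p = 1.49e-14; adjusted p = 0.207 with an estimated correlation). Cell cycle genes stood at -0.14 (3 lower adjusted over the list alone, camera adjusted p = 1.34e-13; adjusted p = 0.207 with an estimated correlation) and macrophage markers -0.16 (2 lower adjusted over the list alone, camera adjusted p = 2.4e-06; adjusted p = 0.266 with an estimated correlation). The members with the smallest p, none past the threshold, were Myl2 (0.36 ± 0.06), Des (0.26 ± 0.06) and Tnnc1 (0.30 ± 0.07) of the sarcomere, and Ndufa3 (0.34 ± 0.08), Ndufb9 (0.22 ± 0.05) and Ndufa6 (0.25 ± 0.07) of complex I. Those of the other pair of lists were Mcm5 (-0.32 ± 0.08), Aurka (-0.24 ± 0.06) and Kif4a (-0.32 ± 0.08) of the cell cycle, and Cd14 (-0.45 ± 0.09), Lcp1 (-0.29 ± 0.07) and Ctss (-0.25 ± 0.08) of macrophages. The other 11 lists had medians between -0.06 and 0.05. Higher among them were oxidative stress (4 members higher adjusted over the list alone), fetal and hypertrophy genes (3), calcium handling (2, and 1 lower), mitochondrial fatty acid oxidation (1), fatty acid uptake (1), and glycolysis, intercalated disc and erythroid markers (0 each), and lower were inflammatory genes (2) and the unfolded protein response and p53 targets (0 each), all with camera adjusted p of 5.03e-05 to 0.0496 and an adjusted p of 0.207 to 0.543 with an estimated correlation. The other 15 lists did not pass, with camera adjusted p of 0.0947 to 0.905.

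The sarcomere, oxidative phosphorylation, cell cycle, macrophage, oxidative stress and fetal lists passed at 10 µg/ml in all 12 omissions of an array, and the other 9 lists did not. Their medians moved by more than 1.5 times for macrophage markers without 10 µg/ml replicate 1 (-0.075; per-array medians -0.229, -0.014 and -0.1), the sarcomere without control replicate 3 (0.101) and oxidative phosphorylation without 10 µg/ml replicate 2 (0.069). Oxidative stress stood at 0.031 without control replicate 3 and at 0.072 and 0.03 without 10 µg/ml replicates 1 and 2. Among the other 9 lists such moves gave 0.088 for glycolysis and 0.054 for mitochondrial fatty acid oxidation without control replicate 1, and -0.03 for the unfolded protein response, -0.027 for inflammatory genes and 0.028 for calcium handling without control replicate 2. Without control replicate 3 the glycolysis median turned to -0.001, with 0.016 for mitochondrial fatty acid oxidation and 0.023 for intercalated disc. Mitochondrial fatty acid oxidation stood at 0.077 without 10 µg/ml replicate 1, calcium handling at 0.023 and 0.024 and fatty acid uptake at 0.036 and 0.024 without 10 µg/ml replicates 2 and 3. The number of lists was 8 without 10 µg/ml replicate 1 and 8 without 10 µg/ml replicate 3. Without 10 µg/ml replicate 1 the adjusted p was 0.0937 for calcium handling, 0.0911 for erythroid markers, 0.0937 for fatty acid uptake, 0.0911 for inflammatory genes, 0.088 for intercalated disc, 0.0814 for p53 targets and 0.0534 for the unfolded protein response. Without 10 µg/ml replicate 3 it was 0.163 for calcium handling, 0.113 for erythroid markers, 0.257 for fatty acid uptake, 0.202 for glycolysis, 0.169 for inflammatory genes, 0.184 for intercalated disc, 0.169 for mitochondrial fatty acid oxidation and 0.113 for p53 targets. Omission of control replicate 3 gave 0.214 for calcium handling, 0.191 for fatty acid uptake, 0.381 for glycolysis, 0.202 for inflammatory genes, 0.221 for intercalated disc and 0.221 for mitochondrial fatty acid oxidation. Omission of control replicate 2 gave 0.0955 for fatty acid uptake, 0.0664 for inflammatory genes, 0.106 for p53 targets and 0.0664 for the unfolded protein response, and that of control replicate 1 gave 0.177 for erythroid markers and 0.146 for p53 targets. Erythroid markers and p53 targets stood at 0.0646 and 0.124 without 10 µg/ml replicate 2. Fatty acid uptake also stood at 0.0518, 0.0534 and 0.061 without 1 µg/ml replicates 1, 2 and 3 and at 0.0555, 0.057 and 0.0567 without 50 µg/ml replicates 1, 2 and 3, and p53 targets at 0.0502 and 0.0577 without 1 µg/ml replicates 2 and 3 and 0.0535 without 50 µg/ml replicate 3. Array weights gave 0.0789 for fatty acid uptake and 0.0829 each for glycolysis, mitochondrial fatty acid oxidation and p53 targets. With only the compared groups in the fit, fatty acid uptake stood at 0.0904 and calcium handling and p53 targets at 0.0559 each. The p53 list also missed the threshold after a repeated quantile normalization (0.124), median centring (0.0533) and the replicate block (0.0583), and fatty acid uptake after median centring (0.05 when rounded), the block (0.0633) and restriction to genes with 1 probe set (0.064).

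The doses were also compared with each other. Between 10 and 1 µg/ml 2722 probe sets differed, 1163 higher and 1559 lower at 10 µg/ml. Over genes the split was more uneven, with 683 higher and 1318 lower. Vof16 was higher at 10 µg/ml by 1.90 ± 0.13 and Ddit4 by 1.21 ± 0.11, and Fos and Myh3 were lower, at -1.54 ± 0.15 and -1.44 ± 0.13. Cell cycle genes were lower, with 22 of 52 lower and 0 higher, 31 adjusted over the list alone (median -0.21, camera adjusted p = 1.61e-10; adjusted p = 0.729 with an estimated correlation). Oxidative phosphorylation was higher, with 12 of 65 higher and 1 lower, 22 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 1.03e-05; adjusted p = 0.729 with an estimated correlation). Endothelial markers were higher too, with 7 of 14 higher and 0 lower, 8 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.000381; adjusted p = 0.729 with an estimated correlation). Without 10 µg/ml replicate 2 that median was 0.171. Extracellular matrix was higher, with 8 of 42 higher and 0 lower, 10 and 1 adjusted over the list alone (median 0.08, camera adjusted p = 0.00208; adjusted p = 0.729 with an estimated correlation), its median being 0.04 without 1 µg/ml replicate 1. Cholesterol synthesis (4 of 19 lower and 1 higher, 6 and 1 adjusted over the list alone), p53 targets (7 of 31 and 2, 10 and 2) and the unfolded protein response (11 of 37 and 7, 17 and 7) were lower, with camera adjusted p of 0.0313, 0.0338 and 0.0454, and adjusted p of 0.875, 0.729 and 0.729 with an estimated correlation. Their adjusted p ran from 0.000605 to 0.245, 0.0206 to 0.0506 and 0.0217 to 0.129 over omissions of an array. Cholesterol synthesis was lost without 1 µg/ml replicate 3 (0.245) or 10 µg/ml replicate 1 (0.0862), and its median of -0.14 was -0.226 without 1 µg/ml replicate 2 and -0.088 without 10 µg/ml replicate 2. The p53 list was lost without 10 µg/ml replicates 1 (0.0506) or 3 (0.0504), and the unfolded protein response without control replicate 3 (0.0535), 1 µg/ml replicates 2 (0.0581) or 3 (0.129), or 10 µg/ml replicates 1 (0.0777) or 3 (0.0547). The other 23 lists did not pass, with camera adjusted p of 0.0739 to 0.896. The probe set count was 1211 without 1 µg/ml replicate 1, 959 without 1 µg/ml replicate 3 and 1162 without 10 µg/ml replicate 2. It was 637 with only the compared groups in the fit and 4353 with array weights.

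Between 50 and 10 µg/ml 2888 probe sets differed, 1363 higher and 1525 lower at 50 µg/ml. Over genes the balance was the other way, with 1110 higher and 981 lower. Pla2g2a was higher at 50 µg/ml by 2.98 ± 0.24 and Npy by 2.34 ± 0.12, and A2m and Lyz2 were lower, at -2.49 ± 0.24 and -2.15 ± 0.13. Macrophage markers had 20 of 27 lower and 0 higher, 21 adjusted over the list alone (median -0.78, camera adjusted p = 1.57e-20; adjusted p = 0.104 with an estimated correlation). The count for 50 against 10 µg/ml was 1743 after a repeated quantile normalization, 1671 with only the compared groups in the fit and 4549 with array weights.

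Where macrophage markers differed by -0.78 between 50 and 10 µg/ml, 8 other lists also passed camera. Cell cycle genes (11 of 52 lower and 1 higher, 11 and 1 adjusted over the list alone) and extracellular matrix (13 of 42 and 3, 13 and 3) were lower at 50 µg/ml, with medians of -0.13 and -0.08 and camera adjusted p of 3.26e-07 and 0.00252. Inflammatory genes (18 of 42 higher and 3 lower, 23 and 3 adjusted over the list alone), cholesterol synthesis (9 of 19 and 0, 12 and 0) and mitochondrial fatty acid oxidation (6 of 26 and 0, 8 and 0) were higher, with medians of 0.20, 0.23 and 0.16 and camera adjusted p of 4.5e-07, 0.000101 and 0.000954. Endothelial (6 of 14 higher and 1 lower, 7 and 2 adjusted over the list alone), epicardial (2 of 12 and 0, 3 and 0) and oxidative stress lists (12 of 40 and 4, 15 and 5) were higher too, with medians of 0.23, 0.14 and 0.09 and camera adjusted p of 0.0204, 0.0239 and 0.0239. With an estimated correlation the adjusted p was 0.454 for inflammatory genes and 0.513 for the other 7. The last 3 calls were lost without single arrays, endothelial without 10 µg/ml replicate 3 (0.101, with 0.00112 to 0.101 over omissions), epicardial without 10 µg/ml replicate 3 (0.05 when rounded) or 50 µg/ml replicate 1 (0.0602, with 0.0145 to 0.0602), and oxidative stress without 10 µg/ml replicate 1 (0.0547) or 50 µg/ml replicate 2 (0.0567, with 0.0121 to 0.0567). The matrix median was -0.048 without 50 µg/ml replicate 3. The other 21 lists did not pass, with camera adjusted p of 0.0762 to 0.996.

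Between 50 and 1 µg/ml 4869 probe sets differed, 2286 higher and 2583 lower at 50 µg/ml, and 1641 genes were higher and 1921 lower. Pla2g2a was higher by 3.28 ± 0.24 and Npy by 2.40 ± 0.12, and Scg2 and A2m were lower, at -2.54 ± 0.10 and -2.23 ± 0.24. Macrophage markers again were lower, with 20 of 27 lower and 0 higher, 22 lower and 2 higher adjusted over the list alone (median -0.81, camera adjusted p = 2.58e-14; adjusted p = 0.183 with an estimated correlation). Cell cycle genes were lower, with 39 of 52 lower and 1 higher, 45 and 1 adjusted over the list alone (median -0.37, camera adjusted p = 1.33e-18; adjusted p = 0.183 with an estimated correlation). Inflammatory genes (19 of 42 higher and 1 lower, 22 and 1 adjusted over the list alone), endothelial markers (11 of 14 and 1, 11 and 1), oxidative phosphorylation (24 of 65 and 1, 26 and 1) and mitochondrial fatty acid oxidation (9 of 26 and 0, 10 and 0) were higher. Their medians were 0.23, 0.49, 0.14 and 0.14, with camera adjusted p of 7.78e-09, 8.85e-06, 0.000217 and 0.0247, and adjusted p of 0.183, 0.23, 0.742 and 0.742 with an estimated correlation. Mitochondrial fatty acid oxidation was lost without 1 µg/ml replicates 1 (0.0901) or 2 (0.0842) and 50 µg/ml replicates 1 (0.115) or 3 (0.0696), with 0.00189 to 0.115 over omissions of an array. The other 24 lists did not pass, with camera adjusted p of 0.0986 to 0.981. The count for 50 against 1 µg/ml was 3201 without 1 µg/ml replicate 2, 3186 without 1 µg/ml replicate 3, 2949 without 50 µg/ml replicate 2 and 2810 after a repeated quantile normalization. Pla2g2a lost its call in both comparisons when the prior variance followed the mean (adjusted p = 0.254 and 0.15, lowest over its alternatives 9.94e-07 and 8.79e-07). A repeated quantile normalization gave 1.69 and 1.97 for Pla2g2a and 1.33 and 1.42 for Npy in the 2 comparisons, -1.46 and -1.12 for A2m, and -1.20 for Lyz2 against 10 µg/ml.

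The 4 groups differed in 5191 probe sets by the moderated F test, and 3281 probe sets passed the linear contrast over the dose order, 1507 upward and 1774 downward. A change at 50 µg/ml alone can carry this contrast, so the count does not show a graded response. The trend count was 2005 without control replicate 1. The probe sets higher at 50 µg/ml had median changes of 0.05, 0.05 and 0.32 at 1, 10 and 50 µg/ml, and those lower at 50 µg/ml -0.09, -0.06 and -0.38. They were chosen against the same 3 controls, which shifts the lower doses the same way without any effect. Groups simulated with no change at 1 and 10 µg/ml gave medians of 0.01 and 0.01 for the higher set and -0.01 and -0.01 for the lower. In 18.9% and 18.2% of the higher and lower probe sets the 3 doses lay in dose order, against 19.5% and 19.3% in that simulation (16.8% to 22.5% and 16.1% to 21.5% over 50 draws). The simulation took the measured changes at 50 µg/ml as true and drew probe sets independently. It may therefore understate the shift that shared controls bring, and the gap in medians does not show an effect at the lower doses. After a repeated quantile normalization the medians at 1 and 10 µg/ml of the higher set were 0.136 and 0.098, and that at 1 µg/ml of the lower set was -0.159. Without 10 µg/ml replicate 2 the medians at 10 µg/ml were 0.026 and -0.033, and without control replicate 2 the median at 1 µg/ml of the higher set was 0.077. Fold changes over all probe sets, which are not independent replicates, correlated at r = -0.05 between 1 and 10 µg/ml, 0.26 between 1 and 50 µg/ml and 0.37 between 10 and 50 µg/ml. The first of these turned to 0.254 after a repeated quantile normalization and to 0.1 with array weights. With an array left out it ran from -0.181 to 0.235, and it lay above 0 without control replicate 1 (0.057), control replicate 3 (0.029) or 10 µg/ml replicate 2 (0.235). The second was 0.493 after a repeated quantile normalization, and the last 0.24 without 10 µg/ml replicate 2. The covariances were -0.000631, 0.00736 and 0.00644. Simulated unchanged groups that shared simulated controls gave r = 0.5 and a covariance of 0.0031. That simulation gave every group the same spread, which fixes r at 0.5 in advance. The measured spreads were unequal, with distances from the other 2 arrays of 0.0898 to 0.0937 in controls and 0.1045 to 0.175 at 10 µg/ml. The simulated values therefore do not tell whether the doses resemble each other more or less than unchanged groups would. Between 1 and 50 µg/ml, 143 probe sets were higher at both doses and 262 lower at both, where independent lists would share 24.2 and 30.4, and 39 moved in opposite directions (54.3). The 3 controls were too few to be split, and part of the excess may come from sharing them.

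**Figure D4:**
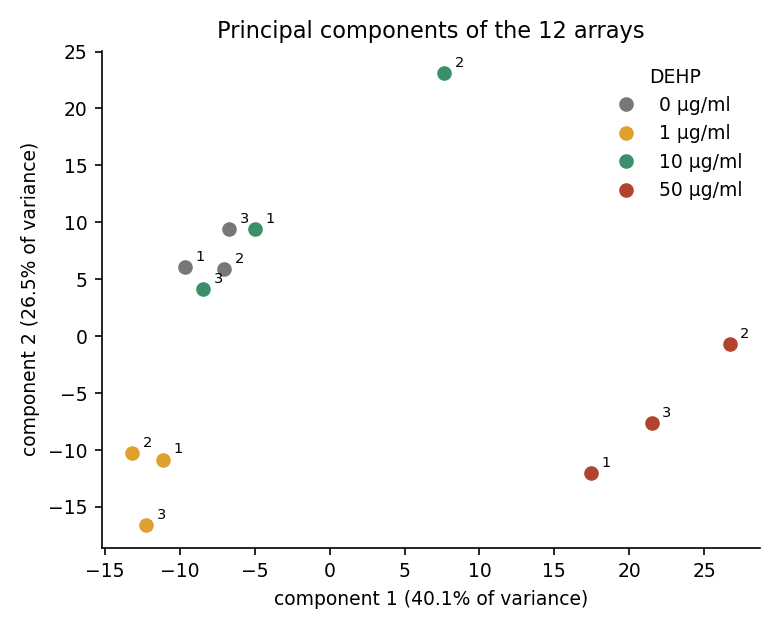
Each point is 1 array, numbered by replicate and coloured by DEHP dose, on the first (40.1% of variance, horizontal) and second (26.5%, vertical) principal components of log2 ratios. The 3 arrays at 50 µg/ml lie at 17.5 to 26.7 on the first component, and 10 µg/ml replicate 2 lies at 7.66 on the first and 23.1 on the second.

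Array 10 µg/ml replicate 2 stood apart from its group. Its root mean square distance from the mean of the other 2 arrays was 0.175, against at most 0.141 for the other 11 arrays, and its endothelial list lay 0.31 above those 2 arrays, so that the median endothelial change per array at 10 µg/ml ran from -0.197 to 0.195. Without it 4278 probe sets changed at 50 µg/ml and 0 at 10 µg/ml.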

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

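The tests of cell type shares, of the pan-macrophage genes and of the immediate early genes were chosen after the results they bear on were seen. The results given first moved in opposite directions at 2 doses, each past its threshold, with the difference between the doses also past it. A test for single outlying arrays was not applied, since groups of 3 are too small for it.

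The cell cycle list was higher at 1 µg/ml, with 3 of 52 members past the threshold, and lower at 10 µg/ml, with 0 past it. The list medians differed by -0.21 (adjusted p = 1.61e-10 by camera, 0.729 with an estimated correlation). The call at 1 µg/ml was lost after quantile normalization again (adjusted p = 0.0988) and without 1 µg/ml replicate 3 (0.0974), with 4.22e-05 to 0.0988 over its alternatives. The same list differed by -0.37 between 50 and 1 µg/ml (adjusted p = 1.33e-18; 0.183 with an estimated correlation). The inflammatory and interferon list was lower at 1 and at 10 µg/ml (6 and 0 of 42 members) and higher at 50 µg/ml (18 members), with differences of 0.20 from 10 µg/ml (adjusted p = 4.5e-07; 0.454 with an estimated correlation) and 0.23 from 1 µg/ml (7.78e-09; 0.183). Its call at 10 µg/ml was lost without control replicates 2 and 3 (0.0664 and 0.202) and without 10 µg/ml replicates 1 and 3 (0.0911 and 0.169), with 0.00285 to 0.202 over its alternatives. The endothelial list was lower at 1 µg/ml (4 of 14 members) and higher at 50 µg/ml (6 members), a difference of 0.49 (adjusted p = 8.85e-06; 0.23 with an estimated correlation), and its call at 50 µg/ml was lost after quantile normalization again (0.0655, with 0.00484 to 0.0655 over its alternatives).

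Among the genes named in the comparisons, 8 were lower at 1 µg/ml and higher at 50 µg/ml or the reverse by more than 1 log2 unit between these doses. The differences of 50 from 1 µg/ml were 1.19 for Ccl2, 1.23 for Ccl7, 1.23 for Cdh5, 1.44 for Fbln1 and 1.98 for Mt2A, which rose at the higher dose, and -2.07 for Aldh1a1, -1.94 for Myh3 and -2.54 for Scg2, which rose at the lower dose. Smaller differences were 0.79 for Sox18, -0.80 for Ndc80, -0.67 for Nuf2 and -0.63 for Tpx2. The differences between the doses kept their calls in all alternatives run, 19 for Mt2A and 20 for each other gene. Calls at 1 µg/ml were lost for Nuf2 and Ndc80 in 11 of these each, Mt2A in 8, Sox18, Tpx2 and Myh3 in 5 each and Cdh5 in 2, with a highest adjusted p of 0.173, 0.154, 0.171, 0.0628, 0.0798, 0.178 and 0.0531 (lowest 0.00724, 0.0049, 0.0159, 0.000767, 0.00298, 0.0138 and 0.00184). At 50 µg/ml Ndc80 lost its call in 7, Sox18 in 6, Nuf2 in 2 and Ccl7 and Cdh5 in 1 each, the last pair after quantile normalization again, with a highest adjusted p of 0.167, 0.089, 0.0593, 0.205 and 0.054 (lowest 0.00653, 0.00126, 0.00133, 0.00326 and 0.00098). Ccl2, Fbln1, Aldh1a1 and Scg2 kept both calls throughout.

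Macrophage and leukocyte markers were lower at 50 µg/ml, with the ratios read as array over median. A lower share of every cell type other than heart muscle cells is argued against, since the endothelial list median lay 1.17 above the macrophage list median relative to control, with a standard error of 0.083. This comparison was chosen after both medians were seen, so it describes them and is no independent test. A mislabelled array is argued against too, since the 3 arrays at 50 µg/ml lay below the other 9 by a gap of 0.62, against a pooled SD of 0.087. Fewer macrophages in these cultures and lower expression per macrophage both stay open and cannot be told apart here. Of 8 pan-macrophage genes (Ptprc, Csf1r, Cd68, Lyz2, Tyrobp, C1qa, C1qb and C1qc) 8 fell, but all 8 are on the list that showed the fall and were chosen after it was seen, so their count decides nothing.

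More probe sets changed at 1 than at 10 µg/ml. A wider spread from 10 µg/ml replicate 2 as the whole reason is argued against, since without that array the count at 10 µg/ml was still 0 (1266 at an unadjusted p under 0.05), against 1906 at 1 µg/ml in the same fit. That fit had 2 arrays at 10 µg/ml and 3 at 1 µg/ml, so the power of the 2 counts was unequal. With 2 control arrays, the count at 1 µg/ml was at its lowest, 283. The array did widen the spread that all comparisons share, since the count at 1 µg/ml was 893 with it. Uneven normalization stays open: quantile normalization applied again raised the count at 1 µg/ml to 1692, but with centred probe sets it forces the SD of every array, 0.087 to 0.199 as deposited, to 0.128, which leaves that test without meaning. Handling of the cultures also stays open, at 1 and at 50 µg/ml, and cannot be told apart from dose. Immediate early genes had a median of 0.27 at 1 µg/ml with 9 of 21 higher. Their median was 0.39 with 16 higher at 50 µg/ml, and 0.015 with 0 higher at 10 µg/ml. A response to the lower dose itself remains among the open explanations, untested.

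Array 10 µg/ml replicate 2 lay apart from its group. A swap with an array at 50 µg/ml is argued against, since its macrophage list median was -0.01 relative to control, while the highest array at 50 µg/ml stood at -0.924. Uneven normalization stays open: after quantile normalization again its distance was 0.15, no longer above the largest of the other 11 arrays at 0.156, which is what that explanation foresaw before the result was seen, but equal spreads are forced by that step and the reading is therefore set aside. No biological explanation was tested, since the labels separate this array from its group in nothing but its number.

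The splits of 3 against 3 arrays number 10 with the real one included, too few for a share under 0.05. The real probe set counts and the highest among other splits were 893 and 0 at 1 µg/ml, 0 and 0 at 10 µg/ml, 3336 and 0 at 50 µg/ml, 2722 and 0 for 10 against 1 µg/ml, 2888 and 40 for 50 against 10 µg/ml, and 4869 and 0 for 50 against 1 µg/ml. As many probe sets came from 1 of the 10 splits each, the real one, except at 10 µg/ml, where all 10 gave 0. For gene lists, as many came from 2, 1 and 2 splits at 1, 10 and 50 µg/ml, with real counts of 11, 15 and 13 and highest others of 15, 11 and 13. The number of lists called at the preset correlation therefore does not set 1 and 50 µg/ml apart from a wrong split of the arrays. For the dose trend 2 of 100 assignments, the real one included, gave as many as 3281, the highest other reaching 3930. For the test over 4 groups 1 of 100, the real one, gave 5191, the highest other being 1563. Both shares lie under 0.05, which argues against groups that do not differ at all. Shuffling all arrays does not test dose order, so the trend count says nothing about it.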

How the results depend on the processing

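The restriction to genes with 1 probe set was chosen after seeing the data. The direction of the test was kept by all 39 called lists and all named genes past the threshold under each alternative run. Quantile normalization again gave 1692 probe sets at 1 µg/ml, 1 at 10 µg/ml, 1743 for 50 against 10 µg/ml and 2810 for 50 against 1 µg/ml, a correlation of 0.493 between 1 and 50 µg/ml, medians at 1 and 10 µg/ml of 0.136 and 0.098 for probe sets higher at 50 µg/ml, and -0.159 at 1 µg/ml for those lower; by construction it gives all arrays 1 spread. Array weights gave 2542 at 1 µg/ml, 3 at 10 µg/ml, 4353 for 10 against 1 and 4549 for 50 against 10 µg/ml (weight 0.308 for 10 µg/ml replicate 2). Fits with the compared groups alone gave 2178 at 1 µg/ml, 637 (10 against 1) and 1671 (50 against 10). Omission of 10 µg/ml replicate 2 gave 1906 at 1 µg/ml, so its spread in the shared estimate lowered that count. Further causes were not tested. A minimum change of 1.5-fold left, by its construction, 102, 550, 203, 468 and 558 at 1 and 50 µg/ml, 10 against 1, 50 against 10 and 50 against 1. The estimated correlation left 0, 0 and 0 lists. The estimates ran from 0.004 for fatty acid uptake to 0.466 for glycolysis, against the preset 0.01. They were 0.354 for the sarcomere, 0.257 for the cell cycle, 0.24 for oxidative phosphorylation and 0.232 for macrophage markers. For such lists the p-values at the preset correlation rest on a correlation far below the one estimated. Uncalled genes changed sign: Col1a1 to -0.008 (quantile) and -0.002 (median centring), and Ppara to -0.001 (median centring). Without single arrays Ppara ran from -0.093 to 0.142, Nppb from -0.016 to 0.17 and Col1a1 from -0.006 to 0.015. The share of higher calls moved by at most 6.42 points under either scaling, apart from 10 µg/ml.

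Omission of single arrays gave 283 to 1906 probe sets at 1 µg/ml, 0 to 0 at 10, 2199 to 4278 at 50, 959 to 3760 for 10 against 1, 1983 to 3473 for 50 against 10, 2949 to 6328 for 50 against 1, 2005 to 3832 for the trend and 3620 to 6241 over the 4 groups, and 9 to 14, 8 to 15 and 12 to 17 lists at 1, 10 and 50 µg/ml. Where 1 of 3 arrays was left out, 2 remained. The replicate number as a block gave 972, 0, 3293, 2886, 2815, 4839, 3256 and 5085 in the same order, none beyond 1.5 times; it ended the calls of Itgam at 1 µg/ml and of fatty acid uptake and p53 targets at 10 µg/ml. No clear pairing of the samples by number was seen, which does not exclude it. Of 18 same-numbered pairs 4 correlated over 0.1 (-0.226 to 0.395), and 5 of 12 arrays correlated best with their own number. Dose as trend score gave 4738. The moderation with a trend uses the mean of centred values, which the response itself sets, and the robust form and it were run on counts and genes, not on lists. The filter on dim probe sets was not run, and signal over background was not analysed here.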

Other observations

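Cardiac ion channels did not pass as a list at 50 µg/ml, where 10 of 33 members were higher, 5 lower and 18 not past the threshold. Of that list, Abcc9 and Kcnj8, which together form an ATP-sensitive potassium channel and are also found in pericytes, rose by 1.04 ± 0.07 and 0.74 ± 0.10 at 50 µg/ml, and the pacemaker channel Hcn4 by 0.54 ± 0.09. On the calcium handling list, which did not pass either, the T-type calcium channel Cacna1g rose by 0.66 ± 0.07 and the plasma membrane calcium pump Atp2b4 fell by 0.66 ± 0.06. The pericyte marker Rgs5, of the smooth muscle and pericyte list, fell by 0.78 ± 0.06. All these genes were chosen after their values were seen.

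Vof16, Ddit4 and the phosphofructokinase regulator Pfkfb3, chosen after their values were seen, fell at 1 and 50 µg/ml against the same 3 controls. At 1, 10 and 50 µg/ml Vof16 stood at -1.71, 0.19 and -1.85, Ddit4 at -1.17, 0.03 and -1.12, and Pfkfb3 at -0.67, 0.03 and -0.79, with none past the threshold at 10 µg/ml. The difference of 10 from 1 µg/ml passed in each (1.90, 1.21 and 0.70, adjusted p = 1.57e-05, 9.98e-05 and 0.00169), as did that of 50 from 10 µg/ml (-2.04, -1.15 and -0.82, adjusted p = 8.11e-07, 1.65e-05 and 0.000109). On the second principal component the 3 arrays at 1 µg/ml and the 3 at 50 µg/ml lay between -16.6 and -0.663, and the controls and the arrays at 10 µg/ml between 4.16 and 23.1. The median of immediate early genes, 0.27 at 1 µg/ml, divides the doses in the same way and does not tell handling from treatment.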
